A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

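RNA was extracted with a RiboPure yeast kit, polyadenylated RNA was captured on oligo-dT beads and the libraries were sequenced on an Illumina HiSeq, per the labels' protocols. The authors deposited 9 tables, each comparing 2 of the 10 libraries: 5 deletions against the same WT library of experiment 1, htl1Δ against WT in YPD and in YPGR, and YPD against YPGR within WT and within htl1Δ. Reads were processed with TopHat, Cufflinks and Cuffdiff against sacCer3, per the submitters' processing notes; versions are not given in the sources used here. The values for each gene are FPKM, fragments scaled by transcript length and library size, which the authors' Cuffdiff run scaled between the 2 libraries of a table. The same WT library differed between tables by a constant factor, from 0.952 to 0.989, so ratios were taken within a table; levels set side by side from different tables are approximate. The deposited log2 fold change is the log2 ratio of those FPKM without a pseudocount, per the file headers, and was not used for the results here. The p-values and q-values are those of the authors' Cuffdiff test between 2 single libraries, as deposited; the smallest p-value listed is 5e-05. Such a test compares the libraries and not the strains, and it is cited only as the authors' call.

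Each table had 6931 rows, of which 115 named several overlapping genes and were left out, leaving 6816. Gene names came from the RefSeq annotation of the R64 assembly, which matched 5859 identifiers, 5381 of them with the same coordinates; coordinates printed are those of the tables, in sacCer3. A gene was measured in a comparison if its row had the authors' status OK and at least 5 FPKM in 1 of the 2 libraries. Ratios are log2((FPKM + 1)/(FPKM + 1)), with a pseudocount of 1 FPKM, which understates the differences of low genes. A gene listed at 0 in a library is given no ratio by name. Genes were counted as different at an absolute log2 ratio of 1 or more, a 2-fold rule of size and not a test. Whether the sequencing kept strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Members of near-identical families are uncertain, HMRA1 shares its sequence with the a mating-type locus, and FPKM of very short loci is unreliable.

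Depth was estimated from the low values of each library, which fall on multiples of the value of 1 fragment: 84.2% to 90.8% of them were whole to within 0.1. This gave about 9070000 to 11910000 fragments per library, and 1 fragment on a locus of 1000 bp was worth 0.105 to 0.138 FPKM. These are estimates, and no counting interval was made from them.

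Before the data were examined, 37 gene lists, the samples, the comparisons and most of the alternatives below were fixed. For each list with at least 4 measured members, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins; a list stands apart below percentile 2.5 or above 97.5. Of the lists, 1 is counted in the totals but its result, like those of some single genes, is not reported here. Flocculin genes had too few measured members in every comparison of a deletion with WT. The same was done for each chromosome. Genes were named by a fixed rule: the deleted genes; per comparison the 8 highest and 8 lowest ratios among genes the authors' table calls significant; and per list at most 4 members at least 2-fold different, largest first. For the 5 comparisons that share a WT library, 100 simulations of unchanged strains with a shared control gave a correlation and a covariance. The simulated noise was taken from the htl1Δ and WT libraries in YPGR. Alternatives were a pseudocount of 0.1 or 10 FPKM, no filter or one of 20 FPKM, ratios centred on their median, rows naming several genes, rows of any status and the size rule joined with the authors' call. Loci of 300 bp or more, the counts and profiles without mating-type, pheromone, marker and deleted genes, the counts with both limits, and rtt102Δ as the control of 1 strain of each pair were added after the data had been seen.

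The procedure was tested on simulated data made from 5940 genes of the npl6Δ comparison with noise of 0.2 (SD, log2) per library. Of genes changed by 1.5 on the log2 scale 93% passed the 2-fold rule in the right direction and of genes changed by 2, 100%. Of unchanged genes 0.0348% passed, with the same noise for every gene. In the data 1.68% of genes passed in the YPGR pair, in which the authors called 0 genes, so the simulated rate may not hold for real libraries. Of unchanged lists 6% fell outside the percentile range, with noise independent between genes. In the data 12 to 19 of the 36 or 37 lists tested per comparison stood apart, 12 of 36 in the YPGR pair, so standing apart is not specific to the deletions. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.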

Results

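Polyadenylated RNA of budding yeast (Saccharomyces cerevisiae, strain background S288C) was sequenced from 10 cultures to compare strains that lack a subunit of RSC with wild type (WT). RSC is an essential chromatin-remodelling complex that moves and evicts nucleosomes at promoters, and Htl1, Npl6, Rsc1, Rsc2 and Rtt102 are among its subunits. All strains were segregants of heterozygous diploids, per the labels. Experiment 1 held 6 libraries from cultures in logarithmic growth in YPD, a rich glucose medium: WT and the htl1Δ, npl6Δ, rsc1Δ, rsc2Δ and rtt102Δ deletions. The titles of all libraries of experiment 1 give 10 generations. Experiment 2 held 4 libraries of WT and htl1Δ strains that carry GALpr-HTL1, HTL1 under a galactose promoter. These were first grown to saturation in YPGR, taken here as the galactose and raffinose medium, and then kept in YPGR or moved to YPD for 10 generations. Each strain and medium had 1 library, so no difference below has a replicate check, and values describe these libraries. Depth was estimated from the steps between low FPKM values at about 9070000 to 11910000 fragments per library. At that depth 5 FPKM on a locus of 1000 bp stood for about 36 to 47 fragments.

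The deleted genes were nearly absent from their own libraries in experiment 1. HTL1 (YCR020W-B, chromosome III, 155320 to 155556, sacCer3) was at 2.09 FPKM in htl1Δ and 293 FPKM in WT. NPL6 (YMR091C, chromosome XIII, 450058 to 451365) was at 0.344 FPKM in npl6Δ and 99.8 FPKM in WT. RSC1 (YGR056W, chromosome VII, 601661 to 604447) was at 0.0390 FPKM in rsc1Δ and 26.4 FPKM in WT. RSC2 (YLR357W, chromosome XII, 841331 to 844050) was listed at 0 in rsc2Δ and was at 28.4 FPKM in WT. RTT102 (YGR275W, chromosome VII, 1043276 to 1043749) was at 0.380 FPKM in rtt102Δ and 147 FPKM in WT. In the authors' deposited table none of these 5 was called significant in its own comparison, with q-values of 0.481 for HTL1, 0.996 for NPL6, 0.668 for RSC1, 0.998 for RSC2 and 0.132 for RTT102. In experiment 2 HTL1 was not absent from the libraries labelled htl1Δ. It was at 232 FPKM in YPD, 41.8% of the 555 FPKM of WT in that table, and at 2782 FPKM in YPGR, where WT had 2973 FPKM.

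The libraries also differed in mating type and in marker genes. In experiment 1 WT and npl6Δ carried transcripts of the alpha mating type, and htl1Δ, rsc1Δ, rsc2Δ and rtt102Δ those of the a type. STE2, the alpha-factor receptor of a cells, was at 6.60 FPKM in WT and 558 FPKM in htl1Δ, while STE3, the a-factor receptor of alpha cells, was at 450 FPKM in WT and 3.11 FPKM in htl1Δ. In experiment 2 the library labelled htl1Δ in YPD was of the a type, with STE2 at 575 FPKM, and the other 3 were of the alpha type. MET17, which encodes a homocysteine synthase, was listed at 0 in htl1Δ, npl6Δ and rtt102Δ, at 155 FPKM in WT of experiment 1 and, in a separately scaled table, at 145 FPKM in the library labelled htl1Δ in YPD. It was listed at 0 in the other 3 libraries of experiment 2. LYS2, a lysine synthesis gene, was at 0.0521 FPKM in htl1Δ, 0.0506 FPKM in rsc1Δ, 0.107 FPKM in rsc2Δ and 27.9 FPKM in WT of experiment 1. In experiment 2 it was at 31.7 FPKM in the library labelled htl1Δ in YPD and at 0.110 FPKM or less in the other 3. The permease genes CAN1 and LYP1 were at 0.131 and 0.0628 FPKM in rtt102Δ. These genes therefore separate strains as well as RSC genotypes, and each total by the 2-fold rule was also taken without them.

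**Figure D1:**
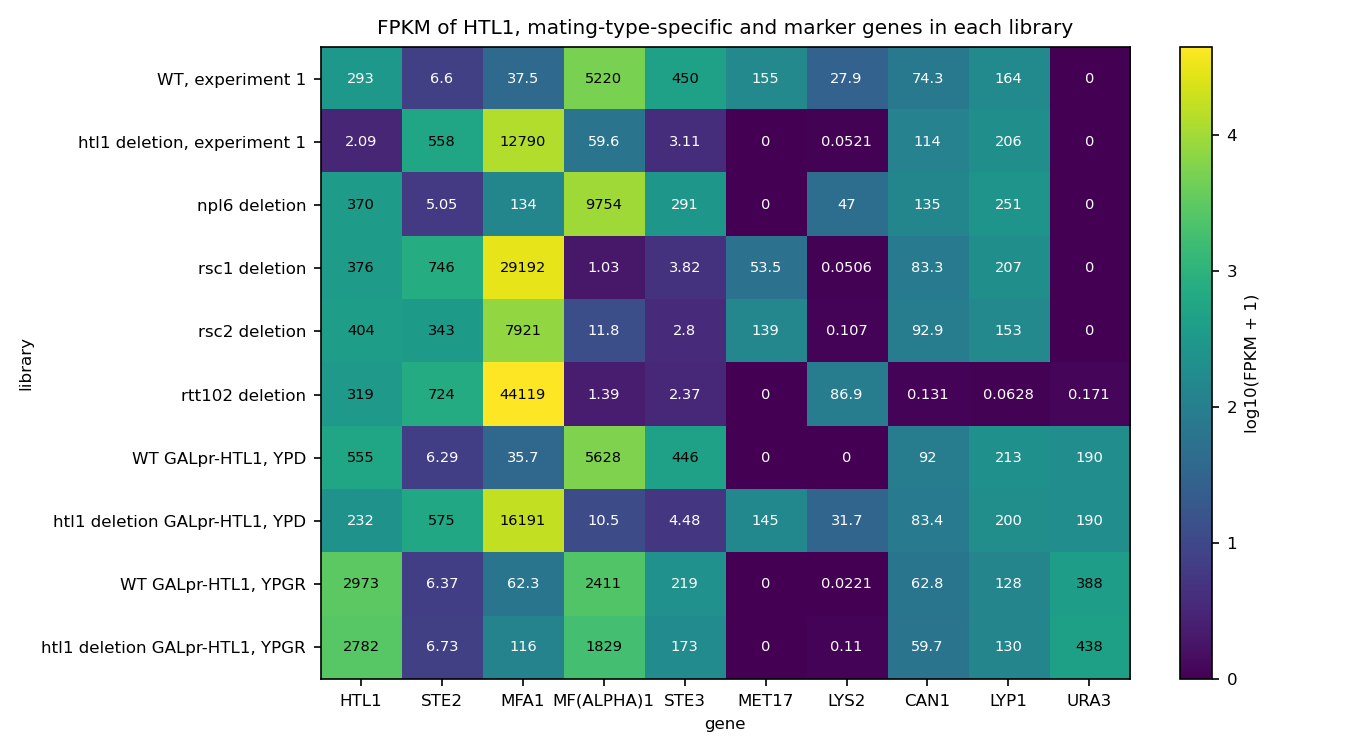
FPKM of HTL1, 4 mating-type-specific genes and 5 marker genes (columns) in each of the 10 libraries (rows), each taken from a table of a deletion against its WT; colour gives log10(FPKM + 1) and the numbers are FPKM. STE2 is at 575 FPKM and MET17 at 145 FPKM in the library labelled htl1 deletion GALpr-HTL1 in YPD, against 6.73 FPKM and 0 in its YPGR counterpart.

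The first comparison asked which transcripts differ when HTL1 is missing. Genes of mitosis were higher in htl1Δ than in WT: all 17 measured G2/M genes had a log2 ratio above 0, with a median of 0.81 (percentile 100 of the random lists), and 4 were at least 2-fold higher. These were the kinase gene KIN3 (1.52), the mitotic cyclin gene CLB1 (1.16), CDC20 (1.08), an activator of the anaphase-promoting complex, and DBF2 (1.08), a mitotic exit kinase. Histone genes were lower, with 10 of 11 below 0 and a median of -0.58, and HHF2, a histone H4 gene, was at -1.07. Ribosomal protein genes had a median of -0.38, where random lists of equal expression already ran from -0.31 to -0.22, while ribosome biogenesis genes had a median of 0.36, with 49 of 56 above 0.

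Of 38 Gcn4 targets of amino acid synthesis 7 were at least 2-fold higher in htl1Δ and 2 lower, with a median of 0.28. ARG1 (argininosuccinate synthase, chromosome XV, 219211 to 220473) had a log2 ratio of 3.39 and ARG3 (ornithine carbamoyltransferase) 2.98, and LYS2, a marker gene, had -4.78. Iron regulon genes had a median of -0.49, with 5 of 26 at least 2-fold lower and 1 higher, among them the iron oxidase gene FET3 (-1.62), TIS11 (-1.61), the siderophore transporter gene ENB1 (-1.52) and the reductase gene FRE1 (-1.41). Chaperone genes had a median of -0.50 with members on both sides: HSP12, which encodes a small membrane-associated stress protein, was at 622 FPKM against 44.9 FPKM in WT (3.76), whereas BTN2, a factor of protein sorting and aggregate handling, was at -2.56 and HSP82 at -1.18. Among wall genes 4 of 28 were at least 2-fold higher, led by PIR3 (2.94) and SED1 (1.43). DNA damage response genes had a median of 0.41, with 10 of 12 above 0. In the phosphate regulon 5 of 16 were at least 2-fold higher and 1 lower, with PHO89 at 1.86 and PHO5 at 1.72, and the median of 0.20 (percentile 97.03) did not stand apart. The cell wall gene TIR1 was at -3.19, YOR338W at 3.32 and ARO5 (YGL117W) at 3.27.

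In all, 235 of 6044 genes measured were at least 2-fold higher in htl1Δ and 173 lower. The authors' deposited table called 18 genes higher and 14 lower, at q-values from 0.0132, and 284 had an unadjusted p under 0.05. With a pseudocount of 10 FPKM the count of 408 came to 247.

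The npl6Δ library differed from WT at more genes by the 2-fold rule, and it shared the mating type of WT. It did not share the marker genes of WT: MET17 was listed at 0 in npl6Δ and was at 153 FPKM in WT. Amino acid synthesis genes were higher: 11 of 38 Gcn4 targets were at least 2-fold higher and none lower, with a median of 0.64 (percentile 100), among them ARG1 (3.06), ARG3 (2.67) and ARG4 (2.35). Ribosomal protein genes had a median of -0.59, below the -0.34 to -0.10 of random lists of equal expression, and ribosome biogenesis genes a median of 0.57, with 54 of 56 above 0. RPS9A (1.62) and RPS9B (-1.03) went opposite ways; they are near-identical paralogs whose reads are hard to assign, so both values are uncertain. HSP12 was at 2575 FPKM against 44.4 FPKM in WT (5.82), NCE103, the carbonic anhydrase gene (chromosome XIV, 559814 to 560479), at 1183 against 97.9 FPKM (3.58) and BTN2 at 19.2 against 202 FPKM (-3.33).

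Chaperone genes had a median of -0.73 in npl6Δ, with 5 of 21 at least 2-fold lower and 3 higher, the latter HSP12, HSP30 (1.84) and HSP26 (1.78). All 11 histone genes were above 0 (median 0.47), and so were 30 of 33 respiratory chain genes (median 0.42), with CYC1, the cytochrome c gene, at 1.09. G1/S genes had a median of 0.41 with the cohesin gene MCD1 at 1.62, and G2/M genes 0.31 with CLB1 at 1.33. Seripauperin and anaerobic wall genes had a median of 0.61, but PAU genes form a near-identical family and their values are uncertain. All 11 pheromone-induced genes were below 0 (median -0.81), 5 of them at least 2-fold, with AGA1 at -2.17, FIG1 at -1.62 and FUS1 at -1.45. That list stood apart downward in 6 of the 7 comparisons of a deletion with WT. Apart from npl6Δ, these comparisons set an a library against an alpha WT library. Mating type may move the list there, so they cannot show whether the shift was particular to npl6Δ. The alpha-specific genes MF(ALPHA)2 (-2.13) and SAG1 (-2.06) were lower in this alpha library too, but of the other 2 MF(ALPHA)1 was at 9754 FPKM against 5164 FPKM in WT, the opposite way, and STE3 at 291 against 445 FPKM. Meiosis and sporulation genes included 7 of 24 at least 2-fold higher, such as SPR28 (2.49) and SPS1 (1.61), while their median of 0.19 did not stand apart. The glycogen synthase gene GSY1 was at -2.59, the pyruvate kinase gene PYK2 at -2.52, the methionine permease gene MUP3 at -2.62, TIR1 at -2.48 and YKR075C at -2.44. GCV2, a glycine decarboxylase subunit gene, was at 2.80, RCK1, a kinase gene, at 2.74, YOR338W at 3.15 and ARO5 at 2.79.

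The rule gave 280 higher and 195 lower genes of 6051 in npl6Δ. Significance calls in the authors' deposited table numbered 16 higher and 11 lower, at q-values from 0.0150, and 313 genes had an unadjusted p under 0.05. A pseudocount of 10 FPKM gave a count of 272.

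The rsc1Δ and rsc2Δ strains lack paralogous subunits of which each RSC complex holds a single copy. In rsc1Δ ribosome biogenesis genes were higher, with 53 of 56 above 0 and a median of 0.30 (percentile 100), though none was 2-fold higher. Genes of the sulfur and methionine pathway had a median of -0.31, with the methionine synthase gene MET6 at -1.79, MET17 at -1.48 and MUP3 at -1.27. The phosphate regulon had a median of -0.30, with PHM6 at -3.71, PHO12 at -1.52 and PHO5 at -1.15; PHO11 and PHO12 are near-identical, which makes the PHO12 value uncertain. General stress genes had a median of 0.17, and YGP1 (1.58), DDR2 (1.27), SPI1 (1.08) and ALD3 (1.01) were at least 2-fold higher. Wall genes had a median of 0.19 and glycolysis genes -0.17, with no member of either 2-fold different.

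HSP12 was again high in rsc1Δ, at 552 FPKM against 43.8 FPKM in WT (3.63), with HSP30 at 1.82 and YRO2, which encodes a related membrane protein, at 1.79, while BTN2 was at -2.50. ARG3 (1.65) and ARG1 (1.61) were higher, but the median of all 38 Gcn4 targets was 0.10 (percentile 93.66). The IMP dehydrogenase gene IMD2 was at -2.32 and YLR126C at -2.66. COS8, of a near-identical subtelomeric family, was at -2.60 and is uncertain. RCK1 was at 2.19. By the 2-fold rule 123 of 6019 genes were higher and 127 lower. The calls made in the authors' deposited table numbered 14 higher and 18 lower, at q-values from 0.0126, and 221 genes had an unadjusted p under 0.05. With a pseudocount of 10 FPKM the count was 131.

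In rsc2Δ genes of respiration were higher. Of 33 respiratory chain genes 31 were above 0, with a median of 0.62 (percentile 100), and CYC1 (1.48), COX7 (1.25), ATP16 (1.07) and ATP3 (1.06) were at least 2-fold higher. The TCA cycle genes IDH1 (1.37), IDH2 (1.23) and ACO1 (1.21) were at least 2-fold higher, with a list median of 0.32, and glycolysis genes had a median of 0.35 with TDH1 at 1.20. G1/S genes had a median of 0.56, with the G1 cyclin gene PCL1 at 1.39 and MCD1 at 1.33, and histone genes a median of 0.48. Wall genes had a median of 0.40, with 6 of 28 at least 2-fold higher: GSC2, a glucan synthase gene (chromosome VII, 548264 to 553951), was at 103 FPKM against 16.6 FPKM in WT (2.56), and PIR3 (1.49), KDX1 (1.14) and CRH1 (1.13) followed.

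General stress genes in rsc2Δ had a median of 0.29, with 8 of 28 at least 2-fold higher and 1 lower: DDR2 was at 2.09, SIP18 at 1.63 and YGP1 at 1.60, while GSY1 was at -2.07. HSP12 was at 1315 FPKM against 42.8 FPKM in WT (4.91). Iron regulon genes went both ways, with a median of -0.30: FIT2 (2.33) and FIT3 (2.21), wall mannoproteins that retain siderophore iron, were higher, and ENB1 (-1.62) and FET4 (-1.61) lower. DNA damage genes had a median of 0.34, with HUG1 at 1.80 and RNR3 at 1.26. Gcn4 targets had a median of -0.14, the only deletion library of experiment 1 in which it lay below 0, and the member at least 2-fold lower was the marker gene LYS2. The phosphate regulon had a median of -0.32, with PHO5 at -1.36. FDC1 was at -2.88, AGA1 at -2.65 and YKR075C at -2.33. By the 2-fold rule 226 of 6047 genes were higher and 158 lower. Significance calls in the authors' deposited table numbered 13 higher and 14 lower, at q-values from 0.0132, and 259 genes had an unadjusted p under 0.05. A pseudocount of 10 FPKM gave a count of 212.

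Of the deletions of experiment 1, rtt102Δ had the fewest different genes by the 2-fold rule. Amino acid synthesis genes were among those that differed: 11 of 38 Gcn4 targets were at least 2-fold higher and none lower, with a median of 0.17 (percentile 100). ARG3 (chromosome X, 268799 to 269815) was at 148 FPKM against 3.41 FPKM in WT (5.08), LYS9 (saccharopine dehydrogenase) at 1054 against 110 FPKM (3.25), ARG1 at 3.07 and LYS1 at 2.72. CAR2, the arginine catabolic ornithine transaminase gene, was at -1.64. General stress genes were lower, with 25 of 28 below 0 and a median of -0.40, and GSY1 was at -1.37 and SIP18 at -1.10. All 16 phosphate regulon genes were below 0 (median -0.24), with the phosphate transporter gene PHO89 at -1.45 and PHO5 at -1.04, and 23 of 26 iron genes were below 0 (median -0.16), with FIT3 at -1.12 and FIT2 at -1.01. Ribosomal protein genes had a median of 0.08, little above the 0.05 to 0.07 of random lists of equal expression. This library lacked the CAN1 and LYP1 transcripts, which encode the arginine and lysine permeases, so the amino acid genes differed together with those markers. MET17 was listed at 0 in it too, as in htl1Δ and npl6Δ. Only in these deletions of experiment 1 did the median of Gcn4 targets stand apart upward, so deletion and marker cannot be told apart. By the 2-fold rule 70 of 5988 genes were higher and 76 lower. The calls made in the authors' deposited table numbered 21 higher and 9 lower, at q-values from 0.0116, and 136 genes had an unadjusted p under 0.05. The count was 89 with a pseudocount of 10 FPKM, and 83 at loci of 300 bp or more without mating-type, pheromone, marker and deleted genes.

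Lists of the structures that duplicate and divide with the nucleus differed little. Over the 7 comparisons of a deletion with WT, nuclear pore genes had medians from -0.04 to 0.12, kinetochore genes from -0.03 to 0.10, and tubulin and spindle motor genes from 0.02 to 0.16, and none of these lists stood apart in any comparison. Spindle pole body genes had medians from 0.03 to 0.17 and stood apart in 1 comparison, rsc2Δ, where 16 of 19 were above 0 and none was 2-fold different. Genes of the nuclear envelope and membrane remodelling had medians from -0.26 to -0.01, all below 0, the lowest in npl6Δ (percentile 2.74), and stood apart in 1 comparison, rsc1Δ, at -0.19. The RSC subunit genes themselves had medians from -0.15 to 0.08 and stood apart in none, and SWI/SNF genes stood apart in 1, at 0.13 in the YPGR pair. Multidrug resistance genes, with medians from -0.17 to 0.21, and meiosis and sporulation genes, with medians from -0.02 to 0.40, stood apart in none.

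**Figure D2:**
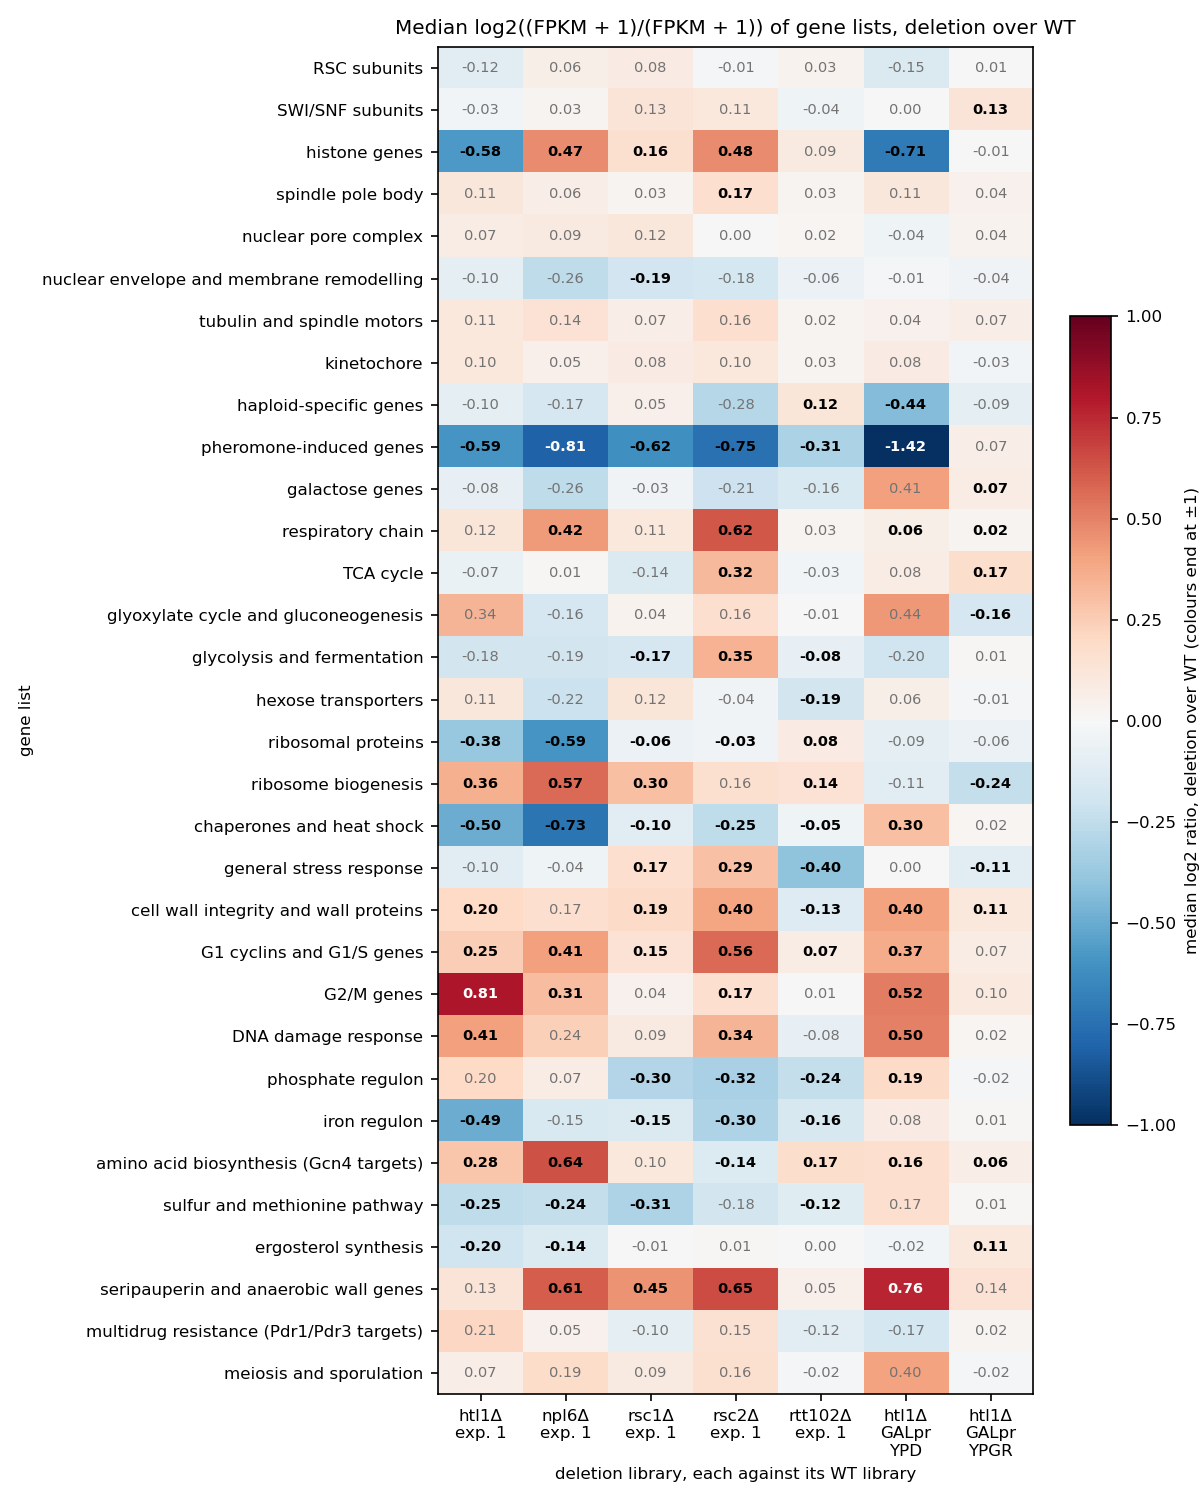
Median log2((FPKM + 1)/(FPKM + 1)) of gene lists (rows) in the 7 comparisons of a deletion library with its WT library (columns); red is higher and blue lower in the deletion, and bold values stand apart from random lists matched on expression. The a-specific, alpha-specific and marker lists lie outside the colour range and are not drawn, and 1 further list is not shown; G2/M genes reach 0.81 in htl1Δ of experiment 1.

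The deletion profiles of experiment 1 were set against each other across genes. Over 5947 genes measured in all 5 comparisons, Pearson correlations of the log2 ratios ran from 0.340 (npl6Δ with rtt102Δ) to 0.637 (htl1Δ with rsc1Δ). They share 1 WT library. Simulated unchanged strains with a shared control had a correlation of 0.4997, and 4 of 10 pairs lay below that value. The simulated noise came from the htl1Δ and WT pair in YPGR and not from the WT library of experiment 1. The covariances, from 0.129 to 0.289, lay above the simulated 0.0143. That value is set by the noise put in. The YPGR pair had a scaled median absolute deviation of log2 ratios of 0.165, against 0.166 to 0.433 in experiment 1. The covariances therefore cannot separate shared changes from a WT library that deviates more than the simulated noise. Between htl1Δ and npl6Δ 109 genes were at least 2-fold higher in both and 76 lower in both, counts that the shared WT library raises by an unknown amount. Without mating-type, pheromone, marker and deleted genes the correlations ran from 0.351 (rsc2Δ with rtt102Δ) to 0.674 (htl1Δ with npl6Δ), and 6 of 10 pairs lay below 0.4997. The WT group had 1 library and could not be split, so how much of these correlations comes from the shared control is not known. With rtt102Δ in place of WT as the control of either strain, the mean correlation over the 6 pairs of the remaining strains was 0.158, from 0.0885 to 0.277, and without mating-type, pheromone, marker and deleted genes 0.265, from 0.143 to 0.424. As rtt102Δ also lacks an RSC subunit, changes that it shares with the other deletions would lower these values. Genes are not independent replicates, and these correlations describe the libraries.

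The second experiment asked what follows when HTL1 expression from the galactose promoter is turned down in glucose. HTL1 was still at 232 FPKM in the library labelled htl1Δ in YPD, against 555 FPKM in its WT. The pair therefore does not set HTL1 absent against present, and it differed at MET17 and LYS2 as well. In the library labelled htl1Δ in YPD, histone genes had a median of -0.71, with 10 of 11 below 0. G2/M genes had a median of 0.52 with DBF2 at 1.10, and G1/S genes 0.37 with CLB6 at 1.38 and CDC6 at 1.33. DNA damage genes had a median of 0.50, with 11 of 12 above 0 and HUG1 (2.24) and RNR3 (1.61), the gene of an inducible ribonucleotide reductase subunit, at least 2-fold higher. This library was of the a type and its WT of the alpha type, and 7 of 12 pheromone-induced genes were at least 2-fold lower, with AGA1 at -3.43, PRM6 at -2.34 and FUS1 at -1.86, and a median of -1.42.

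Wall genes in this pair had a median of 0.40, with 7 of 28 at least 2-fold higher and 1 lower: PIR3 was at 2.47, HSP150 at 1.38, PRM5 at 1.37 and SLT2, the kinase gene of the wall integrity pathway, at 1.24. Phosphate genes had a median of 0.19, with PHO5 at 2.41, PHO89 at 1.87 and PHO11 at 1.86. Chaperone genes had a median of 0.30, with HSP12 at 2.99 and SSA3 at 1.14. SIP18 (2.20), DDR2 (2.17), YGP1 (1.92) and GND2 (1.88) were at least 2-fold higher although the median of all general stress genes was near 0 and did not stand apart. ARG1 was at 1.83. The acetaldehyde dehydrogenase gene ALD6 (chromosome XVI, 432588 to 434090) was at 378 FPKM against 2554 FPKM in WT (-2.75), and PHD1, a transcription factor gene of filamentous growth, at 54.9 against 371 FPKM (-2.73). MFA2 was listed at 0 in the WT library in YPD and was at 21261 FPKM in the library labelled htl1Δ; the locus is so short that FPKM is unreliable there. By the 2-fold rule 230 of 6081 genes were higher and 125 lower. Significance calls in the authors' deposited table numbered 23 higher and 20 lower, at q-values from 0.00931, and 250 genes had an unadjusted p under 0.05. With a pseudocount of 10 FPKM the count was 188.

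In YPGR, where the promoter is active, the library labelled htl1Δ and WT differed at fewer genes by the 2-fold rule, and 12 of 36 lists stood apart. The alpha-specific genes had a median of -0.48, with all 4 below 0 and MF(ALPHA)2 at 46.6% of WT. No list member of the TCA cycle, ergosterol, wall or ribosome biogenesis lists was 2-fold different, although their medians stood apart at 0.17, 0.11, 0.11 and -0.24. Galactose genes had a median of 0.07 (percentile 97.67), just apart. By the 2-fold rule 44 of 6061 genes were higher and 58 lower, and the count was 55 at loci of 300 bp or more, 66 with a filter of 20 FPKM and 52 with a pseudocount of 10 FPKM. The authors' deposited table, made with Cuffdiff, called 0 genes, the smallest q-value being 0.0632, and 77 had an unadjusted p under 0.05. Over 5985 genes the log2 ratios in YPD and YPGR had a Pearson correlation of 0.0239, and 247 genes were at least 2-fold higher and 150 at least 2-fold lower in the YPD ratio than in the YPGR ratio. The strains compared in YPD and in YPGR differed in mating type and markers, so this contrast is not of medium alone.

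The htl1Δ ratios of the 2 experiments could be set side by side because they share no library, although the YPD library of experiment 2 labelled htl1Δ still had HTL1 at 232 FPKM. Over 6018 genes they had a Pearson correlation of 0.339 and a Spearman correlation of 0.279 in YPD, and -0.171 and -0.121 with the YPGR pair over 5964 genes. In YPD 85 genes were at least 2-fold higher in both experiments, where independent lists would share 7.88, and 33 lower in both, where they would share 3.21. With the YPGR pair 6 were higher in both and 6 lower, against 1.03 and 1.45 for independent lists. An excess over independent lists thus arose there although the correlation was negative. The 85 genes included small RNA loci such as snR24, snR59 and tL(GAG)G, where FPKM is unreliable. Experiment 1 and the YPD pair each set an a library against an alpha library. Without mating-type, pheromone, marker and deleted genes the Pearson correlation was 0.218, and 77 genes were higher in both and 23 lower, against 7.30 and 2.59 for independent lists. Genes tied to mating type outside those lists were still among them, such as SST2 of the pheromone response, and YLR041W and YNL146C-A beside mating genes, named after the values were seen. HSP12, ARG1, PIR3, PHO5, PHO89 and DBF2 were among those higher in both. Not all results repeated: the median of chaperone genes was negative in experiment 1 and positive in the YPD pair.

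By the 2-fold rule, though not by the calls in the authors' deposited table, more genes differed between the media than between any deletion and WT. The cultures had first been grown to saturation in YPGR. Whether growth phase also differed between the media, in either strain, was not tested. In the WT GALpr-HTL1 strain 812 of 6080 genes were at least 2-fold higher in YPD than in YPGR and 783 lower. All 7 galactose genes were lower in YPD, with a median of -7.60: the galactokinase gene GAL1 (chromosome II, 279021 to 280607) was at 9.64 FPKM in YPD and 6580 FPKM in YPGR (-9.27), GAL7 at -9.20, GAL10 at -7.90 and the permease gene GAL2 at -7.60. All 33 respiratory chain genes were at least 2-fold lower (median -1.95), such as SDH1 (-3.89) and NDI1 (-2.98), as were 9 of 10 TCA cycle genes (median -1.85), with MDH1 at -2.71, and all 14 glyoxylate cycle and gluconeogenesis genes (median -2.99), with the lactate transporter gene JEN1 at -5.90 and ICL1 at -4.35. Of 28 general stress genes 23 were at least 2-fold lower (median -1.92), led by DDR2 (-4.24) and the glycogen phosphorylase gene GPH1 (-4.23). Ribosome biogenesis genes were higher in YPD, 55 of 56 at least 2-fold (median 1.88), with RPA12 at 3.37 and DBP2 at 2.92, as were 54 of 137 ribosomal protein genes (median 0.94, random lists of equal expression 0.45 to 0.71). The hexose transporter genes HXT2 (5.45), HXT1 (5.20), HXT4 (4.89) and HXT3 (4.42) were higher, while the list of 9 measured had a median of 0.16 that did not stand apart. The authors' deposited table called 1 gene higher and 6 lower, at q-values from 0.0452, and 455 had an unadjusted p under 0.05.

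The libraries labelled htl1Δ gave 851 genes of 6126 at least 2-fold higher in YPD and 805 lower. Galactose genes had a median of -7.36, respiratory chain genes -2.16, TCA cycle genes -2.22, glyoxylate and gluconeogenesis genes -2.25 and general stress genes -1.84, while ribosome biogenesis genes had 1.90 and ribosomal protein genes 0.88. The calls made in the authors' deposited table numbered 6 higher and 8 lower, at q-values from 0.0289, and 436 genes had an unadjusted p under 0.05. Across 6047 genes the ratios of the 2 strains had a Pearson correlation of 0.759 and a Spearman correlation of 0.838; 603 genes were higher in both and 558 lower in both, where independent lists would share 107 and 102. Of all genes 18 were at least 2-fold different in opposite directions, among them HSP12, at -2.16 in WT and 1.87 in htl1Δ, and the mating genes MF(ALPHA)1, SAG1, STE3 and STE6. Phosphate genes were higher in YPD in both strains, with medians of 0.77 and 0.95, and PHO11 was at 4.44 in htl1Δ. All values of this pair also carry the change of mating type between its libraries.

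Because RSC has been linked to ploidy, the median log2 ratio of each chromosome was compared with random gene lists. In htl1Δ of experiment 1 chromosome XIV had a median of -0.21 over 401 genes (percentile 0), and 69.3% of its genes were below 0. Its 4 other chromosomes that stood apart, II, IV, XII and XVI, had medians from 0.04 to 0.05. In the comparisons of npl6Δ, rsc1Δ, rsc2Δ and rtt102Δ with the same WT library the chromosome XIV median was 0.02, 0.01, 0.02 and 0.02, the last standing apart upward (percentile 98.6). In npl6Δ chromosome III had a median of 0.15 over 161 genes (percentile 99.98), and in rsc2Δ chromosome I had -0.12 over 97 genes (percentile 1.00). In the YPD pair of experiment 2 the medians ran from -0.07 to 0.08, 5 chromosomes stood apart and that of chromosome XIV was -0.04, within the random range. FPKM values are scaled within each table, so a change in the number of whole chromosome sets would leave these ratios unmoved and cannot be seen in them.

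**Figure D3:**
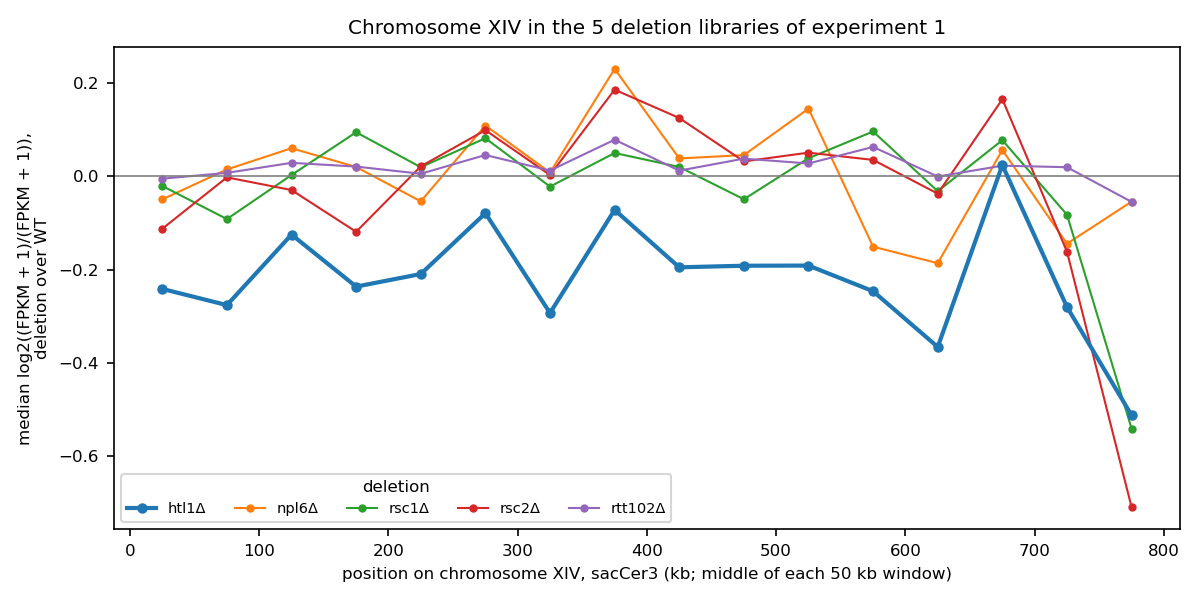
Median log2((FPKM + 1)/(FPKM + 1)) of deletion over WT in windows of 50 kb with 8 or more genes along chromosome XIV (x axis, kb, sacCer3) for the 5 deletion libraries of experiment 1, 1 line each. The htl1Δ line lies below 0 in 15 of 16 windows, down to -0.51 in the last, where rsc1Δ and rsc2Δ are low as well.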

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

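All tests of explanations in this part were chosen after the results they concern had been seen. The following contrasts between media or strains rest on 1 library each and the differences were not tested. HSP12 had a htl1Δ log2 ratio of 2.99 in YPD and -1.07 in YPGR. The alpha-specific mating genes had a median YPD over YPGR ratio of 2.22 in WT and -3.59 in the htl1Δ libraries. The latter were of the a type in YPD and of the alpha type in YPGR, so -3.59 carries that difference of mating type. MFA2, another gene with opposite directions, was left out of these contrasts, a choice made after its values were seen, because it was listed at 0 in the WT library in YPD. Its levels were 21261 FPKM in the library labelled htl1Δ in YPD, and 62.0 FPKM in htl1Δ and 149 FPKM in WT in YPGR.

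Chromosome XIV was lower in htl1Δ of experiment 1. An excess of chromosome XIV transcripts in the shared WT library is argued against by the 4 other deletions, whose lowest chromosome XIV median was 0.00573. Weak genes as its source are argued against as well: without 2-fold genes and genes under 20 FPKM the median over 319 genes was -0.20. This says nothing about a few strongly different genes, which hardly move a median whether kept or not. Fewer copies of chromosome XIV in part of the htl1Δ culture may account for the pattern, since 93.8% of the windows of 50 kb lay below 0. This stays a hypothesis, because DNA content was not analysed here and the pattern was found and tested on the same library.

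The mating-type and marker genes of the library labelled htl1Δ in YPD differed from those of its YPGR counterpart. A mixture with an alpha strain in the YPD library is argued against, since its highest alpha-specific gene stood at 2.52% of WT. A mixture of 2 strains of the a type would leave these genes low as well and was not tested. Loss of HTL1 raising MET17 and LYS2 is argued against as well: of the 5 libraries of experiment 1 with HTL1 intact, MET17 was at 10 FPKM or more in 3 and LYS2 in 3, a test revised after its values were seen. Different segregants used for the YPD and the YPGR culture may account for it, since mating type, MET17 and LYS2 differed together. Of 6 other marker genes, 0 lay 10-fold or more apart between the htl1Δ libraries and not between the WT libraries. That count cannot decide the question, because segregants need not differ at those genes and LEU2 was listed at 0 in every library.

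HTL1 was present in the library labelled htl1Δ in YPD. Galactose induction carried over is argued against, since GAL1 was at 0.931 times its FPKM in htl1Δ of experiment 1, a ratio across separately scaled tables. Basal transcription of the GALpr-HTL1 construct in glucose may account for the level, since WT exceeded it by 323 FPKM, near the 293 FPKM of WT in experiment 1, a separately scaled table. An intact chromosomal HTL1 gene in that strain cannot be told apart from it: the level of 232 FPKM, 41.8% of WT in that table, is near 293 FPKM too. In the comparison of media within htl1Δ, HTL1 was at 242 FPKM in YPD and 2725 FPKM in YPGR. GAL1 was at 12.1 and 7446 FPKM there and GAL10 at 13.3 and 2956 FPKM, so HTL1 fell far less than these native galactose genes. Whether the HTL1 transcript yields protein was not analysed here.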

How the results depend on the processing

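Loci of 300 bp or more, the runs without mating-type, pheromone, marker and deleted genes, both together, and the exchange of controls were chosen after the data had been seen, as were all alternatives for the YPD and YPGR contrast of htl1Δ; the others were planned. With the size rule and the authors' significance call together, the counts were 32 for htl1Δ, 27 for npl6Δ, 31 for rsc1Δ, 27 for rsc2Δ, 30 for rtt102Δ, 42 and 0 for htl1Δ in YPD and YPGR, and 7 and 14 for the change of medium in WT and htl1Δ, by construction fewer. A pseudocount of 10 FPKM, which shrinks the ratios of low genes, gave 247, 272, 131, 212 and 89 genes for the 5 deletions of experiment 1 in that order, 188 and 52 for htl1Δ in YPD and YPGR, and 229 for the difference between the YPD and YPGR ratios. A filter of 20 FPKM gave 66 genes for htl1Δ in YPGR and 247 for that difference, and loci of 300 bp or more gave 55 for htl1Δ in YPGR, with fewer genes tested. Loci of 300 bp or more without mating-type, pheromone, marker and deleted genes gave 83 genes for rtt102Δ and 54 for htl1Δ in YPGR. All other counts of 2-fold genes stayed within 1.5 times. Without mating-type, pheromone, marker and deleted genes the correlation of the htl1Δ profiles of the 2 experiments was 0.218. With rtt102Δ as the control of 1 strain the mean correlation of the deletions was 0.158, or 0.265 without those genes. That exchange would also take out changes that rtt102Δ shares with the other deletions. Of the list medians that stood apart, 830 values under the alternatives kept direction and side, 21 came within the random range and 1 turned: DNA damage genes in the htl1Δ change of medium were at -0.00747 with the filter of 20 FPKM, and the cause was not tested. Of chromosome medians 119 kept, 12 came within the range and 1 turned, chromosome XI in rtt102Δ at 0.00185 with that filter, the cause again not tested. At the estimated depth, 5 FPKM on a locus of 1000 bp stands for about 36 to 47 fragments, and without replicates the spread between cultures is unknown.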

Other observations

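The values in this part were looked at after the main results and no test was planned for them. Transcripts of the genes deleted in laboratory S288C strains as selectable markers were absent or present by library. LEU2 was listed at 0 in all 10 libraries. URA3 was at 190 FPKM in WT and in the library labelled htl1Δ in YPD of experiment 2, at 388 and 438 FPKM in YPGR, and listed at 0 in 5 of the 6 libraries of experiment 1, with 0.171 FPKM in rtt102Δ.

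Among the genes that the htl1Δ profiles of both experiments placed at least 2-fold higher were several of meiosis and sporulation. REC8, the meiotic cohesin gene, was at 1.88 in experiment 1 and 1.69 in the YPD pair, and SPR28, a septin gene of sporulation, at 2.03 and 2.08. SSP1 was at 2.06 and SPS1 at 1.72 in experiment 1. The list as a whole did not stand apart in either, with medians of 0.07 and 0.40.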
